A study of Mus musculus with 13 samples.

How the data were processed

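RNA-seq and ChIP-seq files of 13 mouse libraries were analysed, each the only library of its group. The groups were taken from the sample labels. RNA came from Ogr1 ES cells with and without Smarcad1 RNA interference, from the inner cell mass and from blastocysts. ChIP came from E14 ES cells and, for 1 SMARCAD1 library, from a female ES line. Per the labels' protocols, embryo RNA was amplified before sequencing and E14 cells were grown without feeders.

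The RNA tables held FPKM values (fragment densities scaled to transcript length and library depth) with an interval for each gene, computed by the authors, per the file headers. The submitters' processing notes name TopHat, Cufflinks and Cuffdiff for the ES tables, and Bowtie 0.12.7, TopHat and Cufflinks for the embryo tables and the 2 read files. Transcript tables of the embryo libraries also gave a deposited coverage value per transcript, used here for depth alone. The peak lists gave a deposited score per peak, which ranks peaks within its own list. The submitters' processing notes name Bowtie2 2.1.0, SAMtools and MACS for them, and the build mm9. The control library of peak calling, its threshold and any pooling are not given in the sources used here. H3R26Cit scores began at 40.1 and those of the other lists at 50.0 or just above, so thresholds differed between lists. The read files gave deposited alignments of 100 bp with a constant score, and their rows were counted as reads.

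No replicate existed in any group, so no test across samples was run, no p-value is given and no count model was used. RNA values were compared as log2((value + 1)/(value + 1)), a scale that understates differences of low genes, for genes above 1 FPKM in at least 1 library and with an estimate marked OK in both. A gene was counted when the log2 ratio was at least 1 in size, and counted again where the file-given intervals did not overlap. For each of 19 gene lists fixed before the data were examined, the median log2 ratio was placed among medians of 10000 random lists of the same size matched on mean expression in 20 bins. This percentile describes the 2 libraries and not the conditions. On simulated data with 200 planted genes of 4-fold difference, the size rule recovered 200 with 0 false calls among 11804 genes for the ES comparison. For the embryo comparison it recovered 200 with 0 false among 6730. The simulated noise was smaller than the spread of the real log2 ratios (standard deviation 0.448 for ES and 1.89 for embryo). Planted genes were well expressed, so the simulation gives no rate of false calls for these libraries.

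Peak lists overlapped where peaks shared at least 1 bp. Chance overlap came from 1000 shuffles of the query peaks on their own chromosomes, within 10 kb bins that held a read of either read file (95.8% of bins), or from 100 shuffles for lists above 30000 peaks. Shares carry 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only. Reads were moved from their 5-prime end by 100 bp towards the fragment centre, and reads in peaks were divided by the mean of 200 shuffles. Genes were called near a peak when the peak overlapped the gene span of the RNA files plus 5 kb. Coordinates are mm9, counted from 1. No genome sequence was used here, and exons and introns were not assigned.

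Depth differed between files. Of the H3K4me3 reads, 93.0% had a distinct position and strand, and of the H3K9me3 reads 90.2%. Read numbers behind the peak lists are not given in the sources used here. In the embryo tables the deposited coverage per FPKM was 27.1 times higher in the blastocyst than in the ICM library. The width of the intervals, read as counting error, corresponded to a median of 21.1 fragments for genes above 1 FPKM in the ICM and 711 in the blastocyst. Per gene, the ratio of such fragments per FPKM had a median of 42.9 over 4128 genes and ran from 5.99 (5th percentile) to 213 (95th), so the ratio of depths was not settled. In the ES tables the ratios of 3938 low genes clustered at whole-number ratios of reads. If the cluster near a ratio of 1 held equal reads, 1 read in the knockdown library was worth 1.01 times 1 in the control. A 2-fold gap in depth would give the same clusters, so the relative depth was not settled. ES intervals had a median size of 36.8% (control) and 36.6% (knockdown) of the value on either side.

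The text names, by a rule fixed before the data were examined, Smarcad1 and the Padi genes. In each RNA comparison it names the 10 highest and the 10 lowest ratios among genes with at least 5 FPKM in the higher library, an estimate marked OK in both and intervals apart. Small RNAs, predicted genes and olfactory or vomeronasal receptors are left out. From each list it names 2 to 4 members with the largest differences, and it names Nanog, Klf4, Esrrb, Zfp42, Pou5f1, Sox2, Fgf5, Otx2, Cdx2 and Gata6 where measured. It also names the 5 highest-scoring H3R26Cit peaks and the 5 highest-scoring SMARCAD1 peaks that overlap one. Any other gene named was chosen after its value was seen.

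Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter or a filter of 5 FPKM, ratios centred on the median of all genes, an overlap of 50% of the shorter peak, peaks within 1 kb, the upper part of each list by score, shuffles over whole chromosomes, 1 read per position and strand, reads not moved, and gene spans alone or plus 50 kb. Alternatives chosen after seeing the data were rotation of all peaks of a chromosome by 1 random offset, leaving out bins with over 1000 reads in a library, leaving out the peak with most reads of each list, and leaving out those bins, bins under 25% of the median of reads and 1 Mb windows with at least 5 H3R26Cit peaks. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.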

Results

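The data came from mouse embryonic stem (ES) cells and mouse embryos. SMARCAD1 is a chromatin remodelling ATPase, and H3R26Cit is histone H3 citrullinated at arginine 26, a mark made by the peptidylarginine deiminases (PADI enzymes). Per the labels, the study asked whether SMARCAD1 and H3R26Cit lie at the same sites in ES cells and what SMARCAD1 does in the switch between pluripotent states. There were 13 libraries with 1 library per group, so no difference below has a replicate check. Of the 4 RNA libraries, 2 came from Ogr1 ES cells with and without Smarcad1 knockdown, 1 from the inner cell mass (ICM) and 1 from whole blastocysts. Of the 9 ChIP libraries, 7 were given as peak lists and 2 as aligned reads. The peak lists were H3R26Cit in untreated E14 ES cells (363 peaks), SMARCAD1 in control E14 cells (1279), in a female ES line (21605), in E14 cells treated with the PADI inhibitor Cl-amidine (561) and in Smarcad1 knockdown E14 cells (59749), H3K27ac in knockdown cells (49951), and H3K9me3 in Cl-amidine-treated cells (49347). The read files were H3K4me3 (18054100 reads) and H3K9me3 (13633514 reads) in knockdown E14 cells.

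Smarcad1 mRNA was examined first, since it checks the knockdown label. Smarcad1 stood at 18.9 FPKM in the knockdown library (file-given interval 12.7 to 25.1) and at 35.0 FPKM in the control (24.2 to 45.9). The log2 ratio was -0.86 and the intervals overlapped by a narrow margin. Ratios of low genes did not settle the relative depth of the ES libraries, since a 2-fold gap would give the same ratios. Genes listed at 0 numbered 6116 in the control and 5608 in the knockdown library.

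Primitive endoderm genes were lower in the Smarcad1 knockdown library, and genes of the post-implantation epiblast and the neuroectoderm were mostly higher. All 16 measured primitive endoderm genes were lower, 12 of them by at least 2-fold, with a median log2 ratio of -1.86. Cubn, an endocytic receptor of the visceral endoderm, stood at 0.266 FPKM against 18.3, and the endocytic adaptor Dab2 was lower too (log2 -2.97). The transcription factors Gata4 (0.533 against 10.1 FPKM) and Gata6 (0.326 against 6.46) and the basement membrane collagens Col4a1 (7.03 against 58.8) and Col4a2 (3.49 against 31.7) were also lower. The list's median lay below those of all 10000 random lists of matched expression, and it was -2.87 with a pseudocount of 0.1 and -1.11 with 5.

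Naive pluripotency genes were modestly lower in the knockdown library. Of 20 members, 17 were lower, 2 of them by at least 2-fold, and the median log2 ratio was -0.34, below all random lists. Tbx3 stood at 4.54 FPKM against 23.2 (log2 -2.12) and Tfcp2l1 at 30.1 against 71.5 (-1.22). Klf4 (log2 -0.88), Esrrb (-0.75), Zfp42 (-0.70) and Nanog (-0.34) were lower with overlapping intervals. Gbx2 went the other way, at 114 FPKM against 43.6. Core pluripotency genes differed little. None of the 10 reached 2-fold, the median was 0.14 at the 88.2 percentile of random lists, Pou5f1 stood at 1343 FPKM against 1194 (log2 0.17) and Sox2 at 199 against 234 (-0.24).

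Of 15 measured genes of the post-implantation (primed) epiblast, 13 were higher in the knockdown library and 4 by at least 2-fold, with a median log2 ratio of 0.70, above all random lists. The kinase gene Pim2 stood at 59.3 FPKM against 12.0, the neural cadherin gene Cdh2 at 7.94 against 1.87 and Pou3f1 at 23.1 against 7.59, and Sox3, a neural and epiblast factor, had a log2 ratio of 1.65 with overlapping intervals. Otx2, an epiblast transcription factor, was lower (4.03 against 9.95 FPKM, log2 -1.12), and Fgf5 lay below the filter in both libraries (0.296 and 0.0834 FPKM), as did the trophectoderm regulator Cdx2 (0.862 and 0.323). Of 7 neuroectoderm genes, 4 were at least 2-fold higher and the median was 1.07, above all random lists. The neural progenitor factors Sox1 (17.1 against 3.10 FPKM) and Pax6 (5.88 against 0.615) led this list, and Sox21 followed at 4.63 against 0.835. This median depended on the filter, at 0.04 over 14 genes with none (94.4 percentile), and was 0.63 with a pseudocount of 5.

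**Figure D1:**
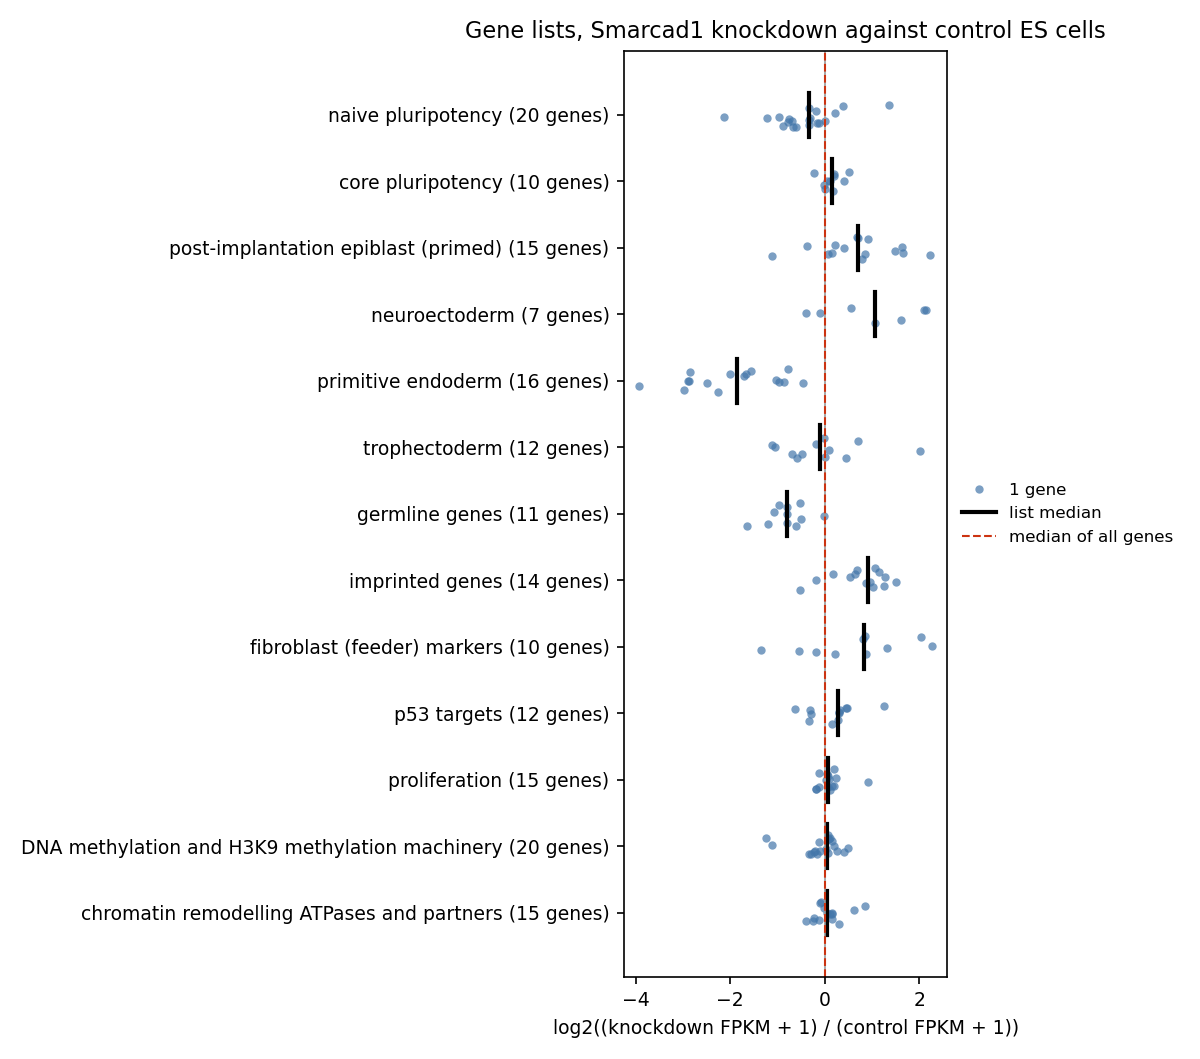
Each point is a gene of a list fixed in advance, placed at the log2 ratio of knockdown over control ES cells, with the list median as a black bar and the median of all genes as a dashed line. Primitive endoderm lies lowest, with a median of -1.86 over 16 genes, while proliferation genes centre on 0.08.

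Across the transcriptome, 11986 genes passed the filter, and 185 were at least 2-fold higher and 192 at least 2-fold lower in the knockdown library. Intervals did not overlap for 100 of the higher and 89 of the lower genes. The median log2 ratio of all genes was 0.00 and 96.9% of genes lay within 2-fold. Among genes with intervals apart, the highest ratios belonged to Efnb2 (ephrin B2, log2 2.55), Hoxa3 (2.32), Hoxb2 (2.32), the intermediate filament gene Vim (2.28), Pim2 (2.22), Cntfr (2.19), Wt1 (2.18), Cyp2b23 (2.16), Sox1 (2.14) and Pax6 (2.09). The lowest belonged to Srgn (serglycin, -4.43), Cubn (-3.93), Dab2 (-2.97), Col4a1 (-2.90), Col4a2 (-2.86), Gata4 (-2.85), the water channel gene Aqp8 (-2.59), Gata6 (-2.49), Amn (-2.26) and Tbx3 (-2.12).

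Germline genes were lower in the knockdown library in all 11 measured members, with a median log2 ratio of -0.80 below all random lists. Rpl10l stood at 7.12 FPKM against 24.5 and Tex11 at 2.04 against 5.96, and a pseudocount of 5 gave a median of -0.39. Imprinted genes were mostly higher. Of 14 members, 12 were higher and 6 by at least 2-fold, the median was 0.91 above all random lists, and the growth inhibitor Cdkn1c (151 against 52.8 FPKM), Mest (83.9 against 34.0) and the noncoding RNA Meg3 (163 against 77.4) were examples. A pseudocount of 5 gave a median of 0.60. In the DNA and H3K9 methylation list the median was 0.05 at the 63.2 percentile, yet the DNA demethylation enzymes Tet1 (21.9 against 53.1 FPKM) and Tet2 (9.33 against 21.5) were at least 2-fold lower.

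Markers of fibroblasts, the usual feeder cells of ES cultures, were higher in the knockdown library in 7 of 10 measured members, with a median log2 ratio of 0.84 above all random lists. Vim (172 against 34.7 FPKM), Tagln (19.9 against 4.07) and Col1a1 (3.57 against 0.826) were at least 2-fold higher, while Thy1 was lower (2.62 against 8.28). The median depended on low values, at 0.24 over 13 genes with no filter, 0.24 with a pseudocount of 5 and 2.01 with 0.1. The epithelial to mesenchymal transition list, which also holds Vim and Cdh2, had a median of 0.16 at the 97.3 percentile, with Zeb2 higher (2.97 against 0.465) and Cldn6 lower (13.7 against 35.4). It turned to -0.04 at the 32.6 percentile over the 6 genes above 5 FPKM. In the p53 target list the median was 0.29 at the 99.99 percentile, and Perp, a cell adhesion gene, alone reached 2-fold (41.1 against 16.8 FPKM), with Sesn1 next at a log2 ratio of -0.64.

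The remaining lists stayed near 0 or held few genes. None of 15 proliferation genes (median log2 0.08) and none of 15 remodeller genes (0.05) reached 2-fold, with the cyclin gene Ccnd1 (79.2 against 41.3 FPKM) and Plk1 (log2 0.25) farthest out among the former and Chd3 (11.7 against 6.00) and Chd7 (log2 0.62) among the latter. Trophectoderm genes had a median of -0.10 at the 17.6 percentile, with Id2 higher (102 against 24.6 FPKM) and Atp1b1 lower (30.2 against 66.3), and stood at 0.00 with no filter and -0.18 above 5 FPKM. The interferon list held 4 measured genes with a median of 0.01 (-0.03 over 13 genes with no filter), and Ifitm3 (104 FPKM against 73.2) and Ddx58 (log2 -0.34) differed most. Of 3 mesoderm genes the median was -0.75, with Cdx1 at 1.05 FPKM against 3.74 and Eomes at -0.75, and it turned to 0.16 over all 15 list genes with no filter and was -1.17 and -0.29 with pseudocounts of 0.1 and 5. Padi2 (log2 -0.55), Padi3 (-0.89) and Padi4 (-0.55) were lower with overlapping intervals (median -0.84 with a pseudocount of 0.1 and -0.24 with 5), and Padi1 and Padi6 lay below the filter. Among oocyte markers Zp3 alone passed the filter (1.34 against 2.12 FPKM), and no gene of the 2-cell-like list passed it. The genes past 2-fold depended on the pseudocount, to 326 higher and 387 lower at 0.1 and to 65 and 58 at 5.

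The embryo libraries were compared to set the ICM, the source of ES cells, against the whole blastocyst, which also holds trophectoderm. Core pluripotency genes were higher in the ICM and trophectoderm genes lower. Of 8 measured core genes, 7 were at least 2-fold higher, with a median log2 ratio of 2.04 at the 96.3 percentile of random lists. Pou5f1 stood at 801 FPKM in the ICM (773 to 829) and 9.11 in the blastocyst (8.76 to 9.46), Utf1 at 37.1 against 2.59, Dppa4 at 51.9 against 8.31 and Trim28 at 756 against 116. Sox2 stood at 3.54 FPKM against 1.26. The log2 ratio of Pou5f1 was 6.31, far above the list median. Whole blastocysts hold ICM cells too, and the source of so large a ratio was not tested. Of 15 trophectoderm genes, 10 were at least 2-fold lower in the ICM, with a median of -1.22 at the 0.08 percentile (-2.20 with a pseudocount of 0.1 and -0.71 with 5).

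The keratin gene Krt8 stood at 6.07 FPKM in the ICM against 90.9 in the blastocyst, and Gata3 at 0.0708 against 11.0. Cdx2, the trophectoderm regulator, was listed at 0 in the ICM and at 3.19 FPKM in the blastocyst, Id2 at 0 and 23.4, and the membrane protein gene Tspan8 at 0 and 17.3. A value of 0 in this ICM library does not show absence, since 24616 of 36520 genes stood at 0, among them Rpl26, Rps25 and Ndufaf2, which most cells express. Ly6a (170 against 26.8 FPKM) and Hand1 (4.89 against 0.211) went the other way. Naive pluripotency genes were mixed. Of 15, 6 were at least 2-fold higher and 2 at least 2-fold lower, and the median of 0.88 lay at the 63.8 percentile. Tbx3 (39.9 against 4.15 FPKM), Tcl1 (log2 1.99), Fbxo15 (97.0 against 27.3), Dppa5a (1834 against 539) and Esrrb (3.07 against 1.22) were higher, while Zfp42 (0.916 against 4.34) Klf4 (0.524 against 2.76) and Nanog (2.70 against 3.75) were lower. The naive median depended on the filter, at 0.13 with none and 1.76 above 5 FPKM, and was 0.46 after centring on the median of all genes and 0.38 with a pseudocount of 5. Of 10 primitive endoderm genes, 3 were at least 2-fold higher, Sparc (87.0 against 13.6) among them, and 3 lower, including Dab2 (0.318 against 14.7), the receptor gene Lrp2 (log2 -2.78) and Gata6 (0.762 against 5.49). Their median was 0.07 and turned to -0.35 with ratios centred on the median of all genes, and to -1.88 above 5 FPKM. Fgf5 was listed at 0 in both libraries and Otx2 lay below the filter.

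**Figure D2:**
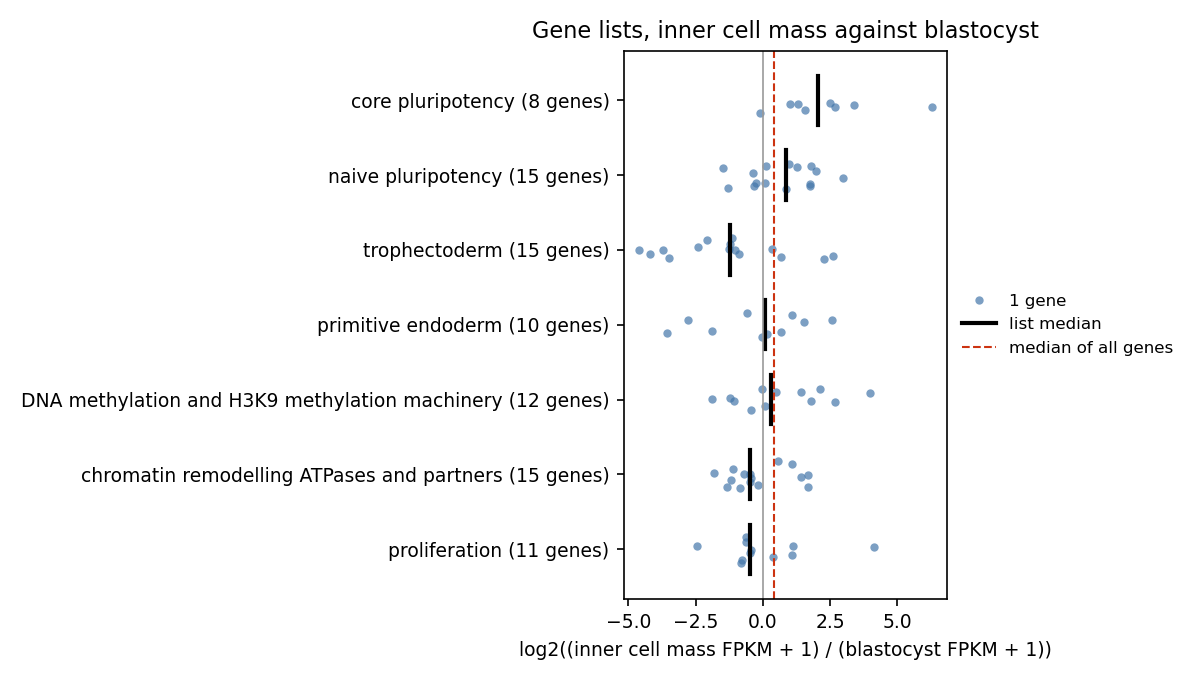
Each point is a gene of a fixed list, placed at the log2 ratio of ICM over blastocyst, with the list median as a black bar and the median of all genes (0.42) as a dashed line. Among the lists shown, core pluripotency genes lie highest with a median of 2.04, and trophectoderm genes lowest with a median of -1.22.

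In all, 7651 of 36520 listed genes passed the filter, and 2941 were at least 2-fold higher and 1749 lower in the ICM, with intervals apart for 2121 and 1674. Genes listed at 0, such as Rpl26 in the ICM, could have an interval of 0 to 0, which is apart from any interval above 0. The counts with intervals apart, and the genes named by that rule, thus include such genes by construction. The median of all genes was 0.42, and ratios centred on it gave 2243 higher and 2416 lower. The correlation of log values across genes, which are not independent replicates, was 0.579. Ribosomal protein genes and their pseudogene copies stood at both ends. Rpl37-ps1 (log2 9.08), Rpl26-ps2 (7.60) and Rpl32-ps (6.71) were highest, while Rpl26 and Rps25 were listed at 0 in the ICM and at 165 and 129 FPKM in the blastocyst, and Rpl32 (-5.25) and Rps15 (-4.88) were low. Reads of these copies cannot be assigned with certainty. The other high genes were Pmf1 (6.67), Pou5f1 (6.31), Lrrc23 (6.05), Zrsr2 (5.94), Mid1 (5.73), Ccdc146 (5.72) and Dhrs4 (5.70). Read from interval widths, the ICM values of Zrsr2, Ccdc146 and Lrrc23 rested on 7.15, 8.89 and 21.6 fragments. Those of the rest of these genes rested on 60.9 (Mid1) to 3343 (Pou5f1). The other low genes were Fam166a (-7.73), Ndufb10 (-5.83), Psma5 (-5.12), Timm44 (-4.95), Id2 and Ndufaf2, the last at 0 in the ICM and 19.5 FPKM in the blastocyst. Smarcad1 itself stood at 1.18 FPKM in the ICM and 1.21 in the blastocyst, and Padi3 and Padi4 were listed at 0 in the ICM and at 0.450 and 0.493 FPKM in the blastocyst.

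The remaining lists had ICM medians within or near the range of random lists. Proliferation genes had a median log2 ratio of -0.49 at the 5.66 percentile, with Pcna higher (101 against 4.82 FPKM) and Top2a lower (4.05 against 26.9). It turned to 0.37 at the 27.9 percentile over the 5 genes above 5 FPKM and was -0.24 with a pseudocount of 5 and -0.91 after centring. Remodeller genes had a median of -0.49 at the 12.4 percentile, with Smarca4 lower (0.848 against 5.49) and Smarca2 higher (2.85 against 0.194), and -0.86 and -0.15 with pseudocounts of 0.1 and 5. In the DNA and H3K9 methylation list the median was 0.29, turned to -0.13 after centring and -0.07 with no filter, and was 1.95 above 5 FPKM, with Zfp809 higher (18.5 against 0.234) and Uhrf1 lower (0.168 against 3.38). For p53 targets the median of 0.06 turned to -0.36 after centring and -0.08 with no filter, with Perp lower (0.625 against 8.33) and Cdkn1a higher (4.08 against 0.0415). Imprinted genes had a median of 1.24 over 5 genes, with Meg3 at 4.83 FPKM in the ICM and listed at 0 in the blastocyst and Igf2r lower (log2 -1.33), and the median was 2.20 and 0.35 with pseudocounts of 0.1 and 5 and 0.00 over 12 genes with no filter. Mesoderm genes had a median of 1.25 over 3 genes (Hand1 and Gsc higher), germline genes -0.20 over 3 (Mael 3.19, Asz1 -1.79) and epithelial to mesenchymal transition genes -0.06 over 5. Of the last, Epcam stood at 12.6 FPKM in the ICM against 57.1, and Snai1 had a log2 ratio of 0.63. With no filter these 3 medians stood at 0.00, -0.01 and 0.00, and after centring at 0.83, -0.62 and -0.48. The post-implantation epiblast, interferon, fibroblast, neuroectoderm, oocyte, PADI and 2-cell-like lists had at most 2 measured genes each, among them Dnmt3b (-1.20), Fn1 (0.77), Bst2 (-1.74) and Ifitm3 (-1.25).

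Ranks within each library were used to set the ES and embryo tables beside each other, since they had been normalized separately. Core pluripotency genes held a median percentile rank of 90.7 in control ES cells, 92.5 in knockdown cells, 87.2 in the ICM and 80.5 in the blastocyst. Naive genes stood at 89.0, 83.2, 73.4 and 77.7. Primitive endoderm genes stood at 59.0 in control ES cells, 17.6 in knockdown cells, 58.4 in the ICM and 57.6 in the blastocyst. Trophectoderm genes stood at 11.5, 15.2, 51.1 and 85.0. Over 12051 shared genes, Spearman's rho across genes was 0.974 between the ES libraries, 0.714 between ICM and blastocyst, 0.537 and 0.523 between the ICM and the control and knockdown ES libraries, and 0.587 and 0.574 between the blastocyst and these. Genes listed at 0 shared a percentile rank of 12.1 in the ICM and 8.71 in the blastocyst. The ICM library was also shallower, at a median of 21.1 implied fragments for genes above 1 FPKM against 711. These values thus do not show which embryo library is more like ES cells.

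H3R26Cit and SMARCAD1 peak lists of E14 cells were compared to see whether the mark and the protein lay together. Of 363 H3R26Cit peaks, 79 overlapped a control SMARCAD1 peak (21.8%, 95% exact binomial interval 17.6 to 26.4%). Shuffled H3R26Cit peaks gave a mean of 0.463 overlaps and a highest of 3. From the other side, 76 of 1279 SMARCAD1 peaks (5.94%, 4.71 to 7.38%) overlapped H3R26Cit. Outside clustered windows and bins with few or very many reads, 25 of 232 H3R26Cit peaks overlapped (10.8%), against a highest shuffle of 3. All such intervals cover counting error only, and neighbouring peaks are not independent.

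The highest-scoring H3R26Cit peak lay on chromosome 1 at 24618367 to 24623237 (mm9), with no listed gene within 5 kb, and overlapped SMARCAD1. It held 0.273 H3K4me3 and 0.105 H3K9me3 knockdown reads per kb, scaled to library size, against 0.403 and 0.388 at shuffled H3R26Cit peaks. The SMARCAD1 peak inside it held 1.46 and 0.679. Whether this or any other peak named here is a collapsed or multi-copy site was not tested. The next peaks lay in Myo3a (chromosome 2, 22443871 to 22446379), in the ribosomal RNA locus Rn45s (chromosome 17, 39979929 to 39985883) and outside genes at chromosome 4, 79648790 to 79651162, and chromosome 13, 85266184 to 85267157. None of these last 4 overlapped control SMARCAD1. The SMARCAD1 peak with the highest score among those with H3R26Cit covered 13229 bp on chromosome X at 166420954 to 166434182, over Mid1, 4933400A11Rik and G530011O06Rik. The others lay on chromosome 8 at 86280281 to 86281274, at 19989496 to 19991588 over 2610005L07Rik and at 19783504 to 19785247, and inside the chromosome 1 peak at 24619397 to 24620153. The chromosome 8 region from 19000001 to 20000000 held 22 H3R26Cit and 16 control SMARCAD1 peaks.

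SMARCAD1 peaks with Cl-amidine were compared with control peaks to ask whether SMARCAD1 binding depends on PADI activity. The list with the inhibitor held 561 peaks over 0.340 Mb, against 1279 peaks over 1.03 Mb in control cells. Of the control peaks, 31 were found with Cl-amidine (2.42%, 1.65 to 3.42%), against a mean of 0.460 and a highest of 4 among shuffles. From the other side, 33 of the 561 Cl-amidine peaks (5.88%, 4.08 to 8.16%) lay in the control list, so the lists shared few peaks in either direction. Of the Cl-amidine SMARCAD1 peaks, 15.7% overlapped H3K9me3 peaks of Cl-amidine-treated cells, against 68.6% of control SMARCAD1 peaks. Control SMARCAD1 peaks with H3R26Cit were found with the inhibitor more often, at 18 of 76 (23.7%, 14.7 to 34.8%) against 13 of 1203 without the mark (1.08%, 0.577 to 1.84%). Of the 18, 14 also lay in the knockdown SMARCAD1 list, and 13 of these 14 in the female-line list as well. By other lists the contrast was smaller, at 6.51% (4.26 to 9.46%) of control peaks in the female-line list against 0.670% (0.246 to 1.45%) of those outside it, and 2.85% (1.85 to 4.18%) with H3K9me3 against 1.49% (0.550 to 3.22%) without. Of the 31 peaks, 25 (80.6%) lay in the female-line list, against 30.0% of all control peaks, and 25 in the knockdown SMARCAD1 list, against 36.8%. The Mid1 peak, present in all 7 lists, and 3 named chromosome 8 peaks were among those found with the inhibitor. Peaks with H3R26Cit also had higher scores, with a median of 89.5 against 64.5. Numbers of peaks depend on depth and caller settings, which are not given in the sources used here for these lists.

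SMARCAD1 peaks of the library labelled knockdown served as a control of the antibody. That list was longer, not shorter, at 59749 peaks over 80.3 Mb. It held 471 of the 1279 control peaks (36.8%, 34.2 to 39.5%), against a shuffle mean of 70.7 and a highest of 99. Of its peaks, 38.3% overlapped H3K27ac in knockdown cells (shuffle mean 5.06%) and 5.27% overlapped H3K9me3 in Cl-amidine-treated cells (shuffle mean 4.47%). Of control SMARCAD1 peaks, 68.6% (65.9 to 71.1%) overlapped those H3K9me3 peaks (shuffle mean 3.76%) and 36.7% overlapped H3K27ac (shuffle mean 3.83%). The lists thus differed in overlap with H3K9me3 and were nearly alike in overlap with H3K27ac. Smarcad1 mRNA was measured in Ogr1 and not E14 cells, so the knockdown of the E14 ChIP library has no RNA check here.

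Most SMARCAD1 peaks of the female ES line overlapped H3K27ac peaks of knockdown E14 cells. No histone mark was measured in the female line itself. The SMARCAD1 list labelled knockdown, used as the antibody control, held 51.0% of the female-line peaks (shuffle mean 5.56%). It is thus not settled that these shared peaks are SMARCAD1 binding. The female-line list held 384 of the 1279 control E14 peaks (30.0%, 27.5 to 32.6%), against a shuffle mean of 17.1 and a highest of 33. Of its 21605 peaks, 59.3% overlapped H3K27ac peaks of knockdown E14 cells and 6.45% overlapped H3K9me3 peaks of Cl-amidine-treated cells, and 75.6% lay within 5 kb of a gene against 47.6% of shuffled peaks. Of control E14 peaks, 44.3% did so, against 45.5%. The line and its genetic background differ from E14 along with the sex, and these cannot be told apart by the lists.

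**Figure D3:**
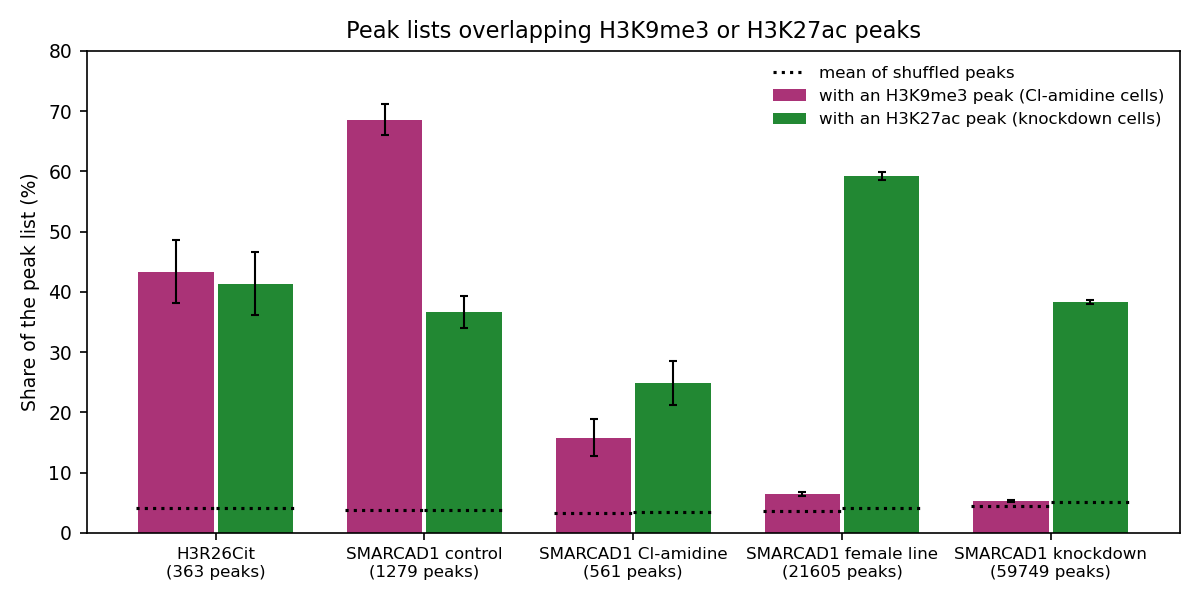
Bars give the percent of each peak list that overlapped an H3K9me3 peak of Cl-amidine-treated E14 cells or an H3K27ac peak of knockdown E14 cells, with 95% exact binomial intervals and the mean of shuffled peaks as dotted lines. Control SMARCAD1 peaks show 68.6% with H3K9me3, and female-line SMARCAD1 peaks 59.3% with H3K27ac.

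Reads of the knockdown E14 libraries were counted at the peak lists to describe marks in the knockdown cells at sites of SMARCAD1 and H3R26Cit. H3K9me3, a mark of heterochromatin, stood 7.24 times above shuffled positions at control SMARCAD1 peaks (5.93 to 7.85 over single shuffles) and 9.72 times at H3R26Cit peaks (1.44 to 12.0). H3K4me3, a mark of promoters, stood at 2.91 times (2.33 to 3.47) and 3.64 times (2.41 to 4.69). None of the libraries was an input (DNA sequenced without an antibody). Sites where reads pile up with any antibody are thus not told apart from sites of the mark. SMARCAD1 peaks with H3R26Cit held H3K9me3 at 21.1 times (10.2 to 26.6) and those without at 5.42 times (0.421 to 6.34). The Mid1 peak alone held 5658 of the reads of the former, 58.4%, and without the peak with most reads in each part the folds were 9.59 (7.11 to 13.2) and 5.23 (3.62 to 5.68). H3K4me3 stood at 5.58 times (2.18 to 8.90) and 2.64 times (2.07 to 3.15). At Rn45s the H3K9me3 density reached 66.4 reads per kb, scaled to library size, and the H3K4me3 density 23.1. The Rn45s peak held 29.1% of the H3K9me3 reads at H3R26Cit peaks, and the fold was 7.22 without it. Outside the peaks named here, the bin at chromosome 2, 98500001 to 98510000, held 6.44% of all H3K9me3 reads. Without bins above 1000 reads the fold was 4.29 at the 353 H3R26Cit peaks left and 5.25 at the 1263 SMARCAD1 peaks left.

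The other SMARCAD1 lists differed in these reads. Female-line SMARCAD1 peaks held H3K4me3 at 10.6 times shuffled positions, and peaks of the knockdown list at 3.83 times. Without the bins above 1000 reads, H3K9me3 stood at 1.56 times at the former and 1.46 times at the latter, and with all bins single shuffles reached down to 0.175 and 0.344 times. Cl-amidine SMARCAD1 peaks held H3K4me3 at 4.45 and H3K9me3 at 11.0 times, which came to 2.90 and 3.61 without the bins above 1000 reads.

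H3K9me3 peaks of Cl-amidine-treated cells were set against H3K9me3 reads of knockdown cells, as 2 perturbations of the same mark. The knockdown reads stood 3.70 times above shuffled positions at those peaks (1.02 to 4.21), and H3K4me3 reads at 0.701 times. Of the peaks, 895 of 49347 (1.81%) overlapped control SMARCAD1 and 159 (0.322%) overlapped H3R26Cit, against shuffle means of 50.8 and 15.8. Without bins above 1000 reads the fold was 4.05 (4.00 to 4.09). No unperturbed H3K9me3 library was analysed here.

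H3K27ac peaks of knockdown cells lay at expressed genes. They held H3K4me3 reads at 6.19 times shuffled positions (4.75 to 6.43), and 72.7% lay within 5 kb of a gene against 47.4% of shuffled peaks. Genes with such a peak had a median of 3.92 FPKM in the knockdown RNA library, and genes without one a median of 0. All 10 core pluripotency genes, 19 of 20 naive genes and 17 of 18 primitive endoderm genes had a peak, as did 69.3% of all genes. The RNA came from Ogr1 and the peaks from E14 cells.

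**Figure D4:**
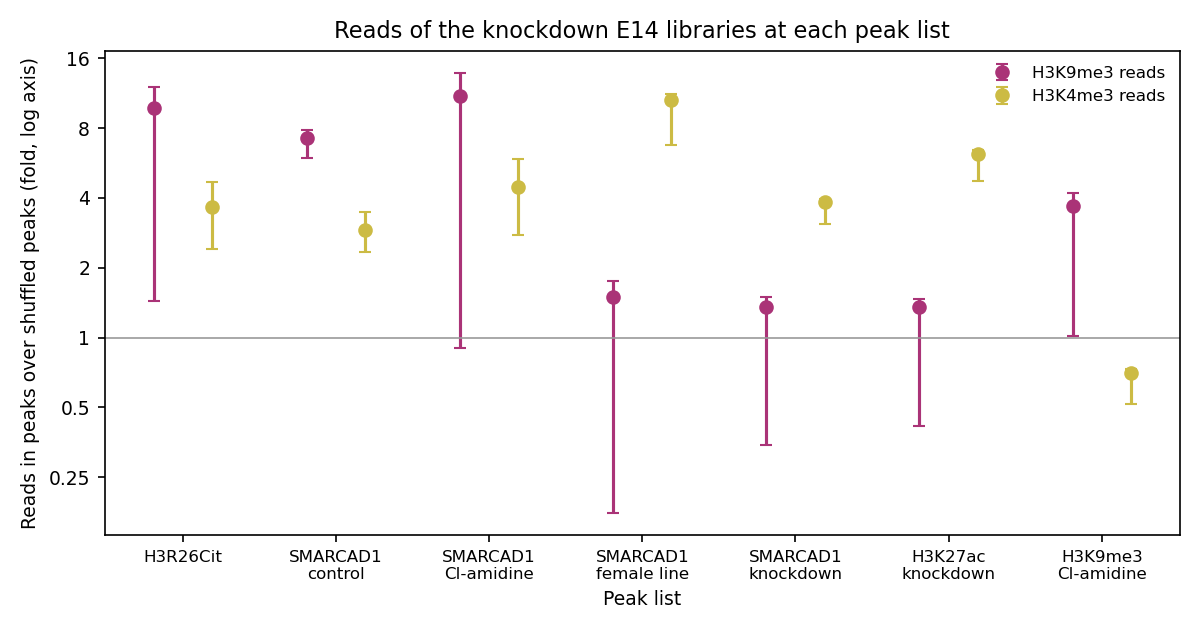
Points give reads of the knockdown H3K9me3 and H3K4me3 libraries in each peak list over the mean of 200 shuffles, on a log axis, and bars the range over single shuffles. H3K4me3 is highest at female-line SMARCAD1 peaks (10.6 times), and H3K9me3 stands at 7.24 times at control SMARCAD1 peaks.

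Genes near control SMARCAD1 or H3R26Cit peaks differed little between knockdown and control RNA. Of the 469 expressed genes with a control SMARCAD1 peak within 5 kb, the median log2 ratio was -0.01 at the 16.5 percentile of matched random sets, and 3 were at least 2-fold higher and 6 lower. Of the 106 expressed genes near H3R26Cit peaks, the median was -0.07 at the 1.83 percentile, with 2 higher and 2 lower. The latter median turned to 0.01 with genes above 5 FPKM and to 0.07 with the upper part of the peaks by score.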

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

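The Cl-amidine SMARCAD1 list held 2 peaks on the mitochondrial genome, which the read counts at peaks left out and the totals of the list included, while the control SMARCAD1 list held 0. No explanation of these peaks was tested.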

How the results depend on the processing

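No paired analysis was possible because each group had 1 library, so leaving out a library or splitting groups was not possible either. Settings were fixed before the data were examined, except the rotation of peaks and the omission of clustered windows, of bins with very many reads and of the peak with most reads, chosen after the results were seen, and the cause of each move was not tested. A pseudocount of 0.1 gave 326 higher and 387 lower genes in the knockdown (185 and 192 with 1), medians of 0.85 for primed epiblast genes (0.70 with 1) and -2.87 for primitive endoderm genes (-1.86 with 1), and -2.20 for trophectoderm genes in the ICM (-1.22 with 1). A pseudocount of 5 gave 65 and 58 genes, medians of 0.54 and -1.11 for the same knockdown lists, 1746 higher and 520 lower genes in the ICM, and -0.0324 for genes near H3R26Cit peaks (-0.0652 with 1). With no filter, primitive endoderm stood at -1.69 in the knockdown, naive genes at 0.13 in the ICM, genes near H3R26Cit at 0.00, and the mesoderm median turned from -0.75 to 0.16. Above 5 FPKM there were 118 lower genes in the knockdown and 739 in the ICM, with medians of -2.38 for primitive endoderm in the knockdown, 1.76 for naive and -1.88 for primitive endoderm genes in the ICM, and genes near H3R26Cit turned to 0.0136. Centring on the median of all genes turned primitive endoderm in the ICM from 0.07 to -0.35. Requiring 50% of the shorter peak gave folds over shuffles of 264 for H3R26Cit in SMARCAD1 (171 at 1 bp), 107 for Cl-amidine (67.4) and 35.0 for the female line (22.4). Peaks within 1 kb gave folds of 94.2, 35.9 and 11.9, and shares of 43.2% for the knockdown (36.8%) and 34.1% for the female line (30.0%). The upper 50% of peaks by score gave 29.7% and 383-fold for H3R26Cit, 157-fold for Cl-amidine, 29.4% for the knockdown, 26.3% for the female line, 2.64 for the log2 FPKM difference at H3K27ac (2.30 with all), and 0.0689, turned, for genes near H3R26Cit. Gene spans plus 50 kb gave -0.0122 for the latter. Without clustered windows and bins with few or very many reads 10.8% of H3R26Cit peaks overlapped SMARCAD1 (21.8%), and without bins with very many reads H3K9me3 stood at 4.29 times at H3R26Cit peaks (9.72). Without the peak with most reads that fold was 7.22, and for control SMARCAD1 peaks with H3R26Cit 9.59 (21.1).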

Other observations

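The tests of depth, of primitive endoderm genes (both) and of clustered windows and bins reported below were chosen after the result was seen, and that of active chromatin before its value was seen. Control SMARCAD1 peaks of E14 cells fell into parts that differed in other marks. Of the 877 that overlapped an H3K9me3 peak of Cl-amidine-treated cells, 228 (95% exact interval 23.1 to 29.0%) also overlapped an H3K27ac peak of knockdown cells. Of the 402 without such an H3K9me3 peak, 241 (60.0%, 55.0 to 64.8%) did. Control SMARCAD1 peaks lay at 4 of 20 naive pluripotency genes, against 2.95% of all genes. All 20 passed the expression filter, and 469 of the 11986 genes that passed it had a control SMARCAD1 peak. Gene length was not matched. H3K9me3 peaks of Cl-amidine-treated cells lay at 10 of 15 germline genes and 10 of 15 imprinted genes, against 30.4% of all genes, and at none of the 10 core pluripotency genes. Of 368 genes with Zfp names, 35.9% had such a peak.

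Chromosome X held 28 of 59749 SMARCAD1 peaks in the knockdown list (0.0469%), 392 of 49951 H3K27ac peaks of knockdown cells (0.785%), 132 of 21605 female-line SMARCAD1 peaks (0.611%), 19 of 1279 control SMARCAD1 peaks (1.49%), 11 of 561 Cl-amidine SMARCAD1 peaks (1.96%), 14 of 363 H3R26Cit peaks (3.86%) and 2186 of 49347 H3K9me3 peaks of Cl-amidine-treated cells (4.43%). Of the 363 H3R26Cit peaks, 110 lay in 12 windows of 1 Mb with at least 5 peaks each. The window on chromosome 1 from 85000001 to 86000000 held 17 H3R26Cit and 12 control SMARCAD1 peaks.

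The SMARCAD1 list of the library labelled knockdown was longer than the control list, the opposite of what loss of the protein would give. If all control peaks were true sites called in the same way, deeper sequencing of the same pattern would have kept nearly all. The knockdown list kept 36.8%. Read numbers, thresholds and the control library of peak calling are not given in the sources used here. That condition could thus not be checked, and depth stays open. Active chromatin as the source of the list stays open. Overlap with H3K27ac was alike, at 38.3% of its peaks (7.57 times shuffles) and 36.7% of control peaks (9.56 times). Its peaks lay near genes more often, with 73.3% within 5 kb (47.6% of shuffled peaks) against 44.3% of control peaks (45.5%). H3K9me3 without the bins above 1000 reads stood at 1.46 times, against 5.25 times at control peaks. H3K4me3 stood at 3.83 times over the whole list and 6.72 times at its peaks with H3K27ac. Peaks without H3K27ac, the only ones tested, held H3K4me3 at 1.34 times (0.945 to 1.41 over single shuffles), a range that spans the value of 1.2 set against this source. That test leaves out the peaks with an active mark, and SMARCAD1 bound at active genes would give the same values, so these cannot be told apart. A wrong label was not tested and stays open.

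Primitive endoderm genes were lower in the knockdown ES library. A scaling difference left in the FPKM values, which are already scaled to library depth, would have moved all genes alike. The median log2 ratio of all genes was -0.0025, but the scaling may itself have set this value near 0. It thus does not exclude a scaling difference. The list's median of -1.86 lay below that of all genes, a gap that moving all genes alike would not give. That all 16 measured members were lower restates the pattern and supports no explanation. Fewer primitive-endoderm-like cells in the knockdown culture and lower transcription within each cell would both give it, so they cannot be told apart in these bulk libraries and both stay open. An effect of the knockdown itself stays open, since each condition had 1 library.

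H3R26Cit and SMARCAD1 lists shared more peaks than shuffled positions. Collapsed or multi-copy regions, where peak callers find signal for any antibody, could give such sharing. Outside the clustered windows and the bins with few or very many reads, 25 H3R26Cit peaks still overlapped SMARCAD1, against a highest shuffle of 3. This argues against those windows and bins as the whole cause. Isolated collapsed or multi-copy sites were not removed and the shuffles do not mimic them, so such sites stay open. The share was 10.8% outside the windows and bins and 21.8% over all regions, so the windows and bins may contribute to it. Open chromatin read by any antibody stays open too. Of control SMARCAD1 peaks with H3R26Cit 77.6% overlapped H3K27ac of knockdown cells, against 34.1% of those without, and of H3R26Cit peaks with SMARCAD1 77.2%, against 31.3% of those without. These shares are not particular to open chromatin. H3R26Cit peaks with SMARCAD1 also lay more often in H3K9me3 peaks of Cl-amidine-treated cells (74.7% against 34.5%), in the knockdown SMARCAD1 list (64.6% against 27.8%) and in the Cl-amidine SMARCAD1 list (24.1% against 4.23%). From the SMARCAD1 side the H3K9me3 shares were 75.0% with H3R26Cit and 68.2% without. Co-location of the mark and the protein also stays open, as a hypothesis.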
